A study of Mus musculus with 4 samples.

How the data were processed

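The data are a gene expression table from RNA sequencing of MC38, a mouse colon cancer cell line. Cells were given PBS or 5-fluorouracil (5-FU) at 1 mM for 24 h, per the labels' protocols, with 2 libraries per group. Total RNA was extracted and libraries were prepared by selection of polyadenylated RNA, per the labels' protocols. The submitters' processing notes name STAR 2.4.1a, Picard 2.9.0 and the mouse genome build GRCm38, without stating the role of each. The program that counted reads, the annotation release and any strand setting are not given in the sources used here.

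The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library size) for 36445 genes in the 4 libraries. Gene IDs were matched to GENCODE release M21 on GRCm38, which held 36295 of them and lacked 150. It supplied the coordinates, gene types and exonic lengths given here. The table showed 26 symbols as calendar dates, and these were restored from their gene IDs. A further check found 156 entries that share a symbol with another entry; gene lists used the entry present in the annotation.

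Depth was estimated from the FPKM steps, because a value times the gene's length is a whole multiple of what 1 read is worth. The commonest smallest step gave about 41.3 and 41.6 M reads in PBS replicates 1 and 2 and 20.8 and 20.6 M in 5-FU replicates 1 and 2. Among values below 100 reads, 65.0%, 65.1%, 63.1% and 63.4% then lay within 0.02 of a whole read in that library order. Lengths in release M21 may differ from those the authors used, so these depths are estimates. For a gene with 2 kb of exons, 3 reads correspond to 0.0363 and 0.036 FPKM in PBS replicates 1 and 2 and to 0.072 and 0.0727 FPKM in 5-FU replicates 1 and 2. Such floors cover counting error only.

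Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested. A two-sided Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold, and every adjusted p of a single gene is from this limma test unless another is named. Log2 differences are on the log2(FPKM + 1) scale and understate the change of low genes; folds are ratios of mean FPKM. A permutation test of a single gene in 2 against 2 libraries cannot give an exact two-sided p below 0.333, so none was run. The labels do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

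Before the data were examined, 26 gene lists were fixed from textbook knowledge, 7 of them primary (p53 targets, type I interferon response, MHC class I antigen presentation, NF-kB and cytokine genes, mitosis, DNA replication, and thymidylate, pyrimidine and folate enzymes). The others covered cytosolic DNA sensing, DNA damage response and repair, ribosome biogenesis, cytosolic ribosomal proteins, ATF4 targets, endoplasmic reticulum chaperones, immediate early genes, checkpoint and NKG2D ligands, replication-dependent histones, cholesterol synthesis, NRF2 targets, glycolysis and hypoxia, mitochondrially encoded genes, apoptosis, senescence, and epithelial, mesenchymal, leukocyte, and endothelial and erythroid markers. The 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which sets a list against all other tested genes, and the p was adjusted over these lists. Camera with an estimated correlation and the fry rotation test were run beside it. With an estimated correlation no list passed (adjusted p = 0.989 for each). That version rests on 2 residual degrees of freedom, so it could hardly pass any group of genes and is weak evidence on each. The 0.989 was reached even where the estimated correlation equalled the preset one (0.01 for MHC class I antigen presentation).

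Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group, counting but not naming unnamed gene models. It also took up to 3 members of each list per direction, or the 2 with the smallest p where none passed. Finally it took Tyms, Cdkn1a, Mdm2, Trp53, Tmem173, Cgas, Ifnb1, Cxcl10, Ccl5, Cd274, Mki67, Dpyd, Umps and Upp1 whatever their values. Other genes named in the text were chosen after their values were seen, and this is said where they appear. Some genes that the rule names are not reported here.

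Choices fixed beforehand and varied were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, eBayes without trend or with robust settings, the replicate number as a block, removal of mitochondrial and ribosomal protein genes, and leaving out each library in turn. A group left with a lone library is assumed to vary like the other group. Added after seeing the data were voom on the estimated reads, thinning of all libraries to the smallest, removal of trends with exonic length or GC content, protein-coding genes only, and removal of genes that begin within 10 kb after the end of an expressed gene. The comparison was also tested on simulated data. The 5 simulated data sets held about 11320 genes, 200 of them changed, with 1 fixed dispersion per group (0.03 in PBS, 0.002 in 5-FU). There, 49% of genes changed 2-fold and 97% of genes changed 4-fold were recovered, and 2.7% of calls were false. The list test called a planted list in 5 of 5 runs and 0 of 100 lists without a change. Genes were drawn independently, while estimated correlations in the real lists reached 0.783 (glycolysis and hypoxia). The 0 of 100 therefore does not cover lists of correlated genes. Nor does the 2.7% carry over to data in which 53.3% of tested genes passed.

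For the closing section, a gene was near-silent at a mean under 1 FPKM in PBS, and its rise was counted where it passed the limma test and reached 3 FPKM in 5-FU. An expressed neighbour had a mean of at least 10 FPKM in PBS. Odds ratios carry 95% intervals with 0.5 added to each cell, and medians and correlations across genes carry 95% bootstrap intervals over genes. Genes are not independent replicates, so these intervals describe the spread across genes only.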

Results

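MC38 is a mouse colon cancer line. Its transcriptome was measured by sequencing of polyadenylated RNA after 24 h with PBS or with 5-FU at 1 mM. 5-FU is a pyrimidine analogue whose metabolites block thymidylate synthase and enter RNA and DNA. Each group held 2 libraries, and the design asks which transcripts differ after 5-FU. Estimated depth was about 41.3 and 41.6 M reads in the PBS libraries and 20.8 and 20.6 M in the 5-FU libraries, so PBS was sequenced 2.0 times as deeply. At least 1 FPKM was reached by 11232 and 11133 genes in PBS and by 11014 and 10981 genes in 5-FU. The PBS libraries differed more from each other (Pearson r = 0.968 across genes, median absolute log2 difference 0.271, 419 genes over 1 log2 apart) than the 5-FU libraries did (r = 0.996, 0.073, 44 genes). The 5-FU pair still differed beyond counting error, with a mean chi-square per gene of 4.13 on the estimated reads (1.53 for genes of 20 to 200 reads), and was counted as 2 samples. This bound covers counting error only and does not show that the libraries came from separate cultures. Between the groups, r lay between 0.86 and 0.893.

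After 5-FU, the checkpoint ligand gene Cd274 rose 8.11-fold, 20 of 40 type I interferon response genes rose and 3 fell, 19 of 22 glycolysis and hypoxia genes fell, and 14 of 22 cholesterol synthesis genes fell and 1 rose. As lists, these 3 passed against other genes at a preset correlation (camera adjusted p = 0.000487, 9.83e-06 and 0.00393). They did not with an estimated correlation (0.989 each), which rests on 2 residual degrees of freedom and could hardly pass any list. Of 11644 tested genes, 2578 were higher and 3628 lower in 5-FU, of which 975 and 1827 differed by at least 1 log2, and 5438 did not pass. In 9428 genes (81%) both 5-FU libraries lay on the same side of both PBS libraries, where 33.3% is expected per gene if libraries were exchangeable. Genes of a library move together, so this share is not evidence from 9428 independent genes. Long genes were lower more often: 61.1% of the 378 protein-coding genes spanning at least 200 kb fell, against 25.4% of the 2497 spanning under 10 kb, with median log2 differences of -0.72 and 0.079. The median log2 difference over all tested genes was -0.097. It moved to 0.013 with median-ratio scaling (3193 higher, 3218 lower), to 0.021 with quantile normalization (2946 and 2825) and to -0.204 without mitochondrial and ribosomal protein genes (2026 and 3968). The counts also moved widely when 1 library was left out, as given below, where the pair that supplies the error changes as well. The median log2 difference was then -0.145 without 5-FU replicate 1 and -0.15 without 5-FU replicate 2. It was 0.008 without PBS replicate 1 and -0.076 without PBS replicate 2.

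**Figure D1:**
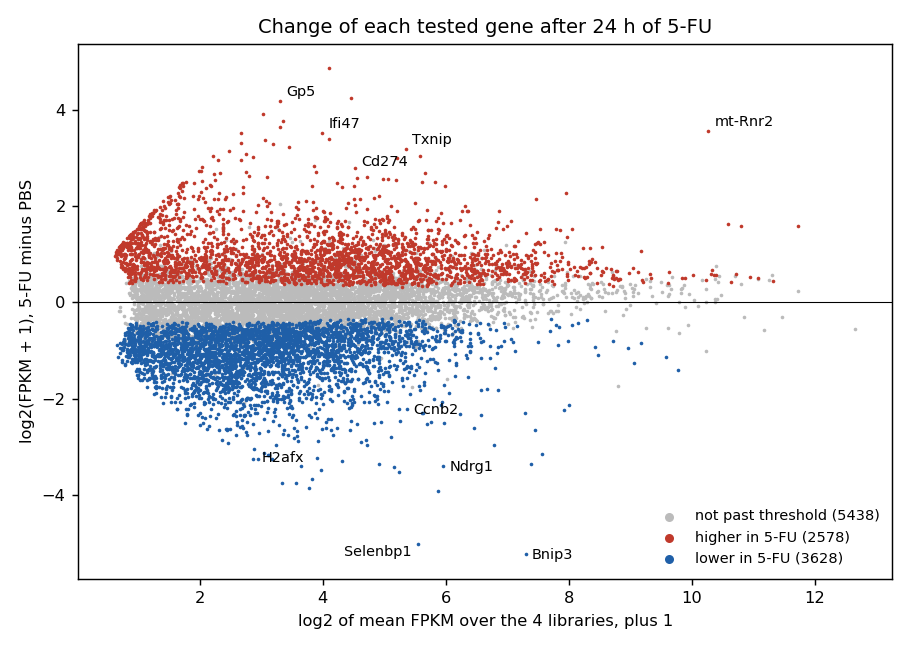
Change of each of the 11644 tested genes after 5-FU. Each point is a gene, placed by the log2 of its mean FPKM over the 4 libraries plus 1 (horizontal axis) and the difference of mean log2(FPKM + 1), 5-FU minus PBS (vertical axis). Red points (2578) were higher and blue points (3628) lower by the limma test, and grey points (5438) did not pass. Bnip3 and Selenbp1 lie lowest, at -5.24 and -5.03.

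Among the largest rises, Ifi47, an interferon-inducible GTPase gene (chromosome 11, 49076587 to 49096974), went from 1.54 ± 0.0514 to 28.25 ± 2.37 FPKM (mean ± SD, n = 2 per group here and below). Txnip, which encodes a thioredoxin-binding protein that restrains glucose uptake, rose 10.2-fold, from 7.11 ± 1.06 to 72.7 ± 1.30 FPKM. The mitochondrial large ribosomal RNA mt-Rnr2 measured 191.9 ± 16.5 FPKM in PBS and 2278 ± 43.7 in 5-FU. Both mitochondrial ribosomal RNAs together summed to 977.3 and 1203 FPKM in the PBS libraries and to 4945 and 4964 FPKM in the 5-FU libraries. Of 62 small nuclear RNAs, 36 were higher and 6 lower (median 1.07 log2), and protein-coding genes held 96.5% and 96.6% of the summed FPKM in PBS and 94.5% and 94.0% in 5-FU. Whether RNA quality or the yield of polyadenylated RNA selection differed between the groups is not given in the sources used here. The remaining rises of the 10 began near zero. Gp5 reached 17.7 ± 0.527 FPKM, Guca2a 14.3 ± 0.272, Asb17os 10.8 ± 0.338, Cdo1 10.6 ± 0.171, Mss51 15.5 ± 0.35, Gng3 18.7 ± 0.432 and the small nucleolar RNA Snord111 18.2 ± 0.257, from means of 0.0275, 0.0204, 0.0242, 0.173, 0.713, 1.14 and 0.406 FPKM in PBS. Gp5 (chromosome 16, 30307685 to 30310779, minus strand) begins 1644 bp after the end of the expressed gene Atp13a3 on the same strand, Cdo1 begins 1749 bp after Atg12 and Mss51 2463 bp after Ppp3cb. Snord111 lies within Sf3b3, and Gng3 and Asb17os overlap Bscl2 and Asb17 on the opposite strand, so their reads cannot be assigned with certainty. Adjusted p was 0.0027 for 9 of these 10 genes and 0.00275 for Mss51, and 5 unnamed gene models ranked among them.

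On the log2(FPKM + 1) scale the largest fall was that of Bnip3, a hypoxia-induced mitophagy receptor gene (chromosome 7, 138890836 to 138909519), which was 45.6-fold lower, at 307.3 ± 136 FPKM in PBS and 6.75 ± 0.514 in 5-FU. Selenbp1 was 51.7-fold lower (89.5 ± 22.4 to 1.73 ± 0.117 FPKM), Bhlhe40, a hypoxia-responsive repressor, 17.6-fold lower (108.9 ± 27.4 to 6.18 ± 0.583), and the transcription factor gene Sox9 36-fold lower (24.8 ± 10.7 to 0.689 ± 0.0873). The growth arrest gene Gas1, Mpp2 and the beta-arrestin gene Arrb1 fell to 0.619, 0.401 and 1.07 FPKM from 21, 17.9 and 25.25. The glycogen synthase gene Gys1, the small GTPase gene Rhob and the collagen lysyl hydroxylase gene Plod2 were 13.6-, 17.7- and 12.8-fold lower. Adjusted p was 0.0027 for 9 of the 10 and 0.00287 for Sox9.

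Of 40 tested genes of the type I interferon response, 20 rose, 3 fell and 17 did not pass, also when adjusted over the list alone (20 and 3), and the median log2 difference was 0.573. The guanylate-binding protein genes Gbp3 and Gbp2 rose 4.89-fold and 4.60-fold (7.89 ± 0.158 to 38.6 ± 2.36 and 7.25 ± 1.57 to 33.4 ± 2.60 FPKM). The chemokine gene Cxcl10 rose from 117.2 ± 53.2 to 322.3 ± 12.9 FPKM (adjusted p = 0.0186, and 0.0761 with no filter on low values), and Ifit3b rose from 0.434 ± 0.0191 to 5.45 ± 1.67. Ifi27 fell 2.15-fold, and the RNA sensor gene Ifih1 and Herc6 fell by 0.954 and 0.801 log2. The chemokine gene Ccl5 measured 17.1 ± 2.41 and 18.5 ± 0.12 FPKM (adjusted p = 0.52). Ifnb1, which encodes interferon beta, was too low to test. It was listed at 0 in both PBS libraries and at 0.0624 and 0.378 FPKM in 5-FU, about 0.974 and 5.84 reads. The list was higher than other genes (camera adjusted p = 0.000487), with adjusted p = 0.989 with an estimated correlation. Without 5-FU replicate 1 or 2 the list held 12 genes higher and 1 lower, with 29 and 7 without PBS replicate 2 and 26 and 10 without PBS replicate 1. Reads of Ifit3b and the Gbp genes may be shared with near-identical paralogs, so their single values are uncertain.

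Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095), rose 8.11-fold, from 4.84 ± 0.297 to 39.2 ± 0.462 FPKM (log2 difference 2.79 ± 0.116 SE, adjusted p = 0.0027). Among 9 tested checkpoint and NKG2D ligand genes, 3 rose and 1 fell (2 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.13). Ulbp1, an NKG2D ligand gene, rose 3.50-fold, Lgals9 rose 1.35-fold at adjusted p = 0.0499, a call lost in 15 of 20 alternative settings, and the phagocytosis checkpoint gene Cd47 fell by 0.649 log2. Of 14 cytosolic DNA sensing genes, 4 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.714). Tmem173, which encodes STING, rose 1.54-fold (5.77 ± 0.121 to 8.91 ± 0.151 FPKM, adjusted p = 0.0203; 0.266 and 0.293 without 5-FU replicates 1 and 2). The inflammasome DNA sensor gene Aim2 rose from 11.7 ± 1.49 to 25.2 ± 0.614 FPKM and the ribonuclease H2 subunit gene Rnaseh2b by 0.631 log2, while Rnaseh2a and Mre11a fell by 0.51 and 0.414 log2. Cgas measured 8.46 ± 3.44 and 15.1 ± 0.0887 FPKM (adjusted p = 0.0606) and passed, higher, in 5 of 20 alternative settings. These were median-ratio scaling (0.0311), quantile normalization (0.0343), replicate number as a block (0.0237) and the fits without PBS replicate 1 or 2. Without a PBS library the error rests on the closer 5-FU pair alone, so those passes carry little weight. Of 18 MHC class I presentation genes, 6 rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.132). The balance was 3 higher and 1 lower with no filter on low values and 3 and 2 without mitochondrial and ribosomal protein genes. It was 3 and 0 without genes after an expressed gene, and 7 and 1 with median-ratio scaling. H2-Q4, the immunoproteasome gene Psmb10 and the proteasome activator gene Psme2 rose by 0.822, 0.902 and 0.793 log2, and the peptide transporter gene Tap2 fell by 0.653 log2. Reads of H2-Q4 may be shared with other H2 genes. Of 19 NF-kB and cytokine genes, 5 rose and 7 fell, likewise adjusted over the list alone (camera adjusted p = 0.976). The balance was 4 higher and 1 lower with no filter on low values and 3 and 4 at a mean of at least 5 FPKM. It was 2 and 5 with the trend with exonic length removed, 2 and 7 without mitochondrial and ribosomal protein genes, and 6 and 7 with median-ratio scaling. Il6 rose from 0.144 to 2.22 FPKM, Csf2 from 0.362 to 1.63 and Ccl2 from 157.4 to 278.1, while Cxcl5, Cxcl3 and Cxcl1 fell by 1.44, 1.25 and 0.928 log2. With PBS replicates 1 and 2 and 5-FU replicates 1 and 2 left out in turn, 6 and 2, 7 and 1, 2 and 0, and 2 and 0 ligand genes were higher and lower, 6 and 2, 5 and 7, 1 and 0, and 0 and 0 DNA sensing genes, 10 and 3, 9 and 3, 0 and 0, and 0 and 0 MHC class I genes, and 9 and 6, 7 and 7, 0 and 1, and 0 and 2 cytokine genes.

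**Figure D2:**
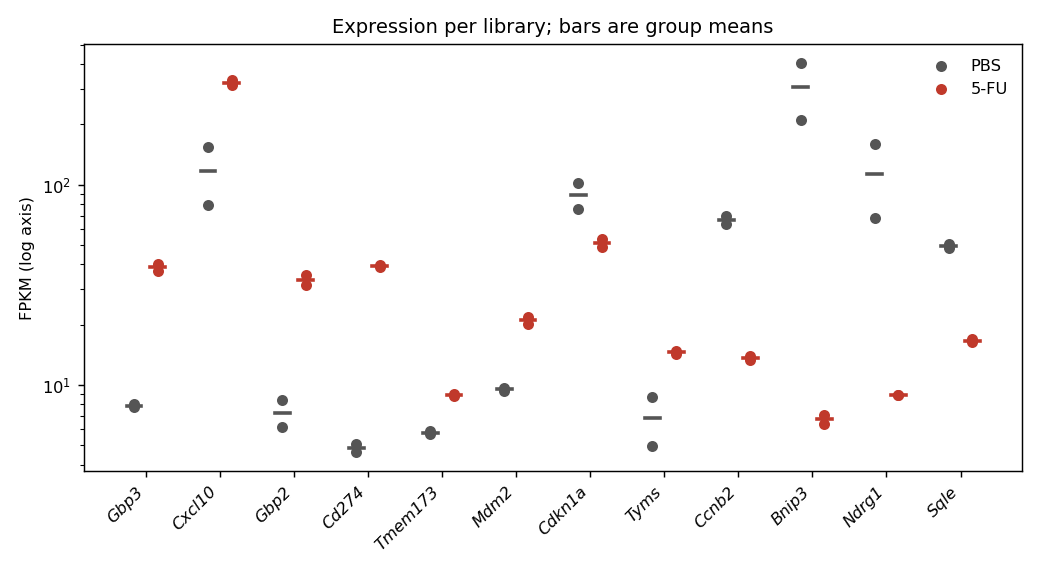
FPKM of 12 genes in each library on a log axis. Points are single libraries, grey for PBS and red for 5-FU, and short bars are group means of 2 libraries. Cd274 lies at 4.63 and 5.05 FPKM in PBS and at 39.6 and 38.9 in 5-FU, and Bnip3 at 211.4 and 403.3 against 6.38 and 7.11.

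All 22 glycolysis and hypoxia genes were tested, and 19 fell, 0 rose and 3 did not pass, with 19 also when adjusted over the list alone. At an unadjusted limma p under 0.05 the count higher was also 0. Besides Bnip3, the stress-responsive gene Ndrg1 fell 12.75-fold (113.7 ± 63.9 to 8.92 ± 0.00474 FPKM), and Pdk1, whose kinase blocks pyruvate entry into the citric acid cycle, fell 13.5-fold (35.0 ± 7.45 to 2.60 ± 0.0747). The median log2 difference was -1.32 (camera adjusted p = 9.83e-06; adjusted p = 0.989 with an estimated correlation). The PBS libraries themselves differed in this list: 21 of the 22 genes were higher in PBS replicate 2 than in PBS replicate 1, by a median of 0.473 log2. Of 22 cholesterol synthesis genes, 14 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. The sterol pathway enzyme genes Nsdhl and Sqle fell by 2.01 and 1.51 log2, and the sterol carrier gene Stard4 fell by 1.93 log2 (29.25 ± 1.20 to 6.92 ± 0.0924 FPKM). Sc5d, a late enzyme of the pathway, rose by 0.582 log2. The list's median was -0.68 (camera adjusted p = 0.00393; adjusted p = 0.989 with an estimated correlation). Without 5-FU replicates 1 and 2 it held 7 and 8 genes lower and 0 higher, without PBS replicate 1 it held 14 lower and 5 higher, and without PBS replicate 2 20 lower and 1 higher.

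Of 33 ribosome biogenesis genes, 11 rose and 1 fell, likewise adjusted over the list alone. The nucleolar GTPase gene Gnl3 rose from 62.9 ± 8.52 to 190.9 ± 10.7 FPKM, the shared RNA polymerase subunit gene Polr1c from 29.4 ± 3.37 to 86.4 ± 0.283 and Nop14 from 56.05 ± 8.29 to 149.9 ± 2.42, while Wdr43 fell by 0.876 log2. The camera adjusted p was 0.0028 (adjusted p = 0.989 with an estimated correlation), 0.146 without PBS replicate 2 (16 higher, 9 lower) and 0.0566 with quantile normalization. Without 5-FU replicates 1 and 2 it counted 4 and 5 genes higher and 0 lower, and without PBS replicate 1 28 higher and 1 lower. Of 33 cytosolic ribosomal protein genes, 9 rose and 0 fell (6 and 0 adjusted over the list alone), and the count lower was 0 under every setting but the one without PBS replicate 1 (21 higher, 2 lower). Rps27l, a p53-inducible ribosomal protein paralog, rose 2.02-fold, Rplp2 rose by 0.905 log2 and Rpl37 by 0.703 log2. The camera adjusted p of this list was 0.000487 (adjusted p = 0.989 with an estimated correlation), 0.0587 without PBS replicate 1 and 0.739 with quantile normalization, where 3 genes passed. Removing the trend with exonic length left 5 (adjusted p = 0.0328). It counted 30 without PBS replicate 2 and 1 without either 5-FU library. Reads of these genes may be shared with pseudogenes. Of 12 mitochondrially encoded protein genes, 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.714). The balance was 0 higher and 4 lower with the trend with exonic length removed, 1 and 1 with quantile normalization, with the GC trend removed or with replicate number as a block, 0 and 1 with no filter on low values, and 5 and 1 with median-ratio scaling. mt-Nd5 rose from 1341 ± 170 to 2025 ± 36.3 FPKM, mt-Nd4 and mt-Nd4l rose by 0.515 and 1.20 log2, and mt-Atp6 fell by 0.842 log2, all 4 with reads that overlapping genes can share. The calls of mt-Nd5 and mt-Nd4 were each lost in 7 of 18 alternative settings. The mitochondrial list held 6 higher and 3 lower without PBS replicate 1, 5 and 5 without PBS replicate 2 and 0 and 0 without either 5-FU library.

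Of 32 p53 target genes, 6 rose, 10 fell and 16 did not pass, likewise adjusted over the list alone. The balance was 8 higher and 7 lower with quantile normalization, 6 and 3 at a mean of at least 5 FPKM and 4 and 3 with no filter on low values. Trp53 itself rose 2.70-fold (31.4 ± 10.9 to 84.5 ± 3.99 FPKM), and Mdm2, which encodes its ubiquitin ligase, rose 2.22-fold (9.50 ± 0.216 to 21.1 ± 1.27, adjusted p = 0.00422; 0.0592 without 5-FU replicate 2). The receptor tyrosine kinase gene Epha2 rose by 1.37 log2. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 0.766 log2 (88.6 ± 19.0 to 51.15 ± 3.30 FPKM, adjusted p = 0.0229). Its call was lost in 3 of 20 alternative settings, those without 5-FU replicate 1 or 2 among them. Trp53inp1, Plk2 and the apoptosome gene Apaf1 fell by 1.45, 1.35 and 1.18 log2. The list did not pass (camera adjusted p = 0.976). Of 33 DNA damage response and repair genes, 4 rose and 15 fell (4 and 16 adjusted over the list alone; camera adjusted p = 0.133, and 0.011 without PBS replicate 2). With the trend with exonic length removed the DNA damage list held 5 higher and 12 lower, and its median moved from -0.592 to -0.271. Gadd45g rose 8.91-fold (7.27 ± 1.47 to 64.8 ± 3.71 FPKM), and Tipin and Exo1 rose by 1.10 and 1.18 log2. The histone variant gene H2afx fell 13.9-fold (26.2 ± 4.91 to 1.88 ± 0.0875 FPKM), Bard1 by 2.00 log2 and the checkpoint kinase gene Atr by 1.94 log2. Of 23 apoptosis regulators, 3 rose and 12 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.212). Bak1, Casp8 and Tnfrsf10b, which promote cell death, rose by 1.27, 1.08 and 0.455 log2. Bid and Apaf1, which also promote it, fell by 1.94 and 1.18 log2, and Cflar, which encodes a caspase inhibitor, fell by 1.26 log2. Leaving out PBS replicates 1 and 2 and 5-FU replicates 1 and 2 in turn gave 12 and 13, 11 and 9, 3 and 0, and 2 and 2 p53 targets higher and lower, 9 and 18, 5 and 24, 2 and 5, and 3 and 5 DNA damage genes, and 6 and 13, 5 and 12, 2 and 1, and 1 and 3 apoptosis regulators.

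Mitotic genes moved in both directions: 6 of 33 rose and 16 fell (7 and 16 adjusted over the list alone), with a median of -0.356 (camera adjusted p = 0.276). With the trend with exonic length removed, 6 rose and 10 fell, with a median of -0.116. The cyclin gene Ccnb2 fell 4.92-fold (66.9 ± 4.55 to 13.6 ± 0.471 FPKM) and the kinesin genes Kif2c and Kif11 fell by 1.37 and 1.05 log2, while the kinase genes Aurka and Cdk1 and the cohesin protector gene Sgo1 rose by 0.813, 0.745 and 0.666 log2. The proliferation marker Mki67 measured 57.5 ± 13 and 43.7 ± 4.87 FPKM (adjusted p = 0.163). Of 38 DNA replication genes, 11 rose and 5 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.212, and 0.0426 without PBS replicate 1). The balance of DNA replication genes was 5 higher and 4 lower with no filter on low values. It was 9 and 8 without mitochondrial and ribosomal protein genes, and 15 and 5 with median-ratio scaling. Rpa2, Orc1 and Fen1 rose by 1.41, 1.32 and 1.30 log2, and E2f1, Gins2 and Pole fell by 1.20, 1.14 and 0.975 log2. Of 29 thymidylate, pyrimidine and folate enzymes, 5 rose and 5 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.976). With no filter on low values 1 of 30 rose and 1 fell, and with median-ratio scaling 6 rose and 5 fell. Tyms, which encodes thymidylate synthase, measured 6.83 ± 2.68 FPKM in PBS and 14.5 ± 0.28 in 5-FU and rose 2.13-fold (adjusted p = 0.029). The Tyms call was lost in 3 of 20 alternative settings, those without 5-FU replicate 1 or 2 among them. The uridine kinase gene Uck1 rose 3.35-fold, while the cytidine deaminase gene Cda and Cad, the first enzyme of pyrimidine synthesis, fell by 1.47 and 1.46 log2. Umps and Upp1, whose enzymes convert 5-FU to nucleotides and nucleosides, did not pass (adjusted p = 0.188 and 0.141). Dpyd, which encodes the enzyme that degrades 5-FU, was too low to test, at 0.0481 and 0.338 FPKM in PBS and 0.0299 and 0.0543 in 5-FU. Of 7 replication-dependent histone genes, 3 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.714), and with no filter on low values 9 of 19 were higher and 1 lower, with the list higher (0.0142). Hist1h4d, Hist1h1e and Hist2h4 reached 2.76, 1.94 and 1.08 FPKM, and Hist2h2be and Hist1h4i fell by 1.20 and 0.978 log2, all with reads that related histone genes can share. Of 62 small nuclear RNAs, 36 were higher and 6 lower in the same libraries, and whether polyadenylated RNA selection differed is not given. The histone values therefore do not show that expression of histone genes itself rose. Without PBS replicates 1 and 2 and 5-FU replicates 1 and 2 in turn, 9 and 18, 7 and 20, 0 and 2, and 0 and 4 mitotic genes were higher and lower, 23 and 9, 16 and 14, 2 and 3, and 3 and 1 DNA replication genes, 13 and 9, 6 and 15, 1 and 2, and 1 and 2 pyrimidine and folate enzymes, and 3 and 3, 3 and 1, 0 and 0, and 0 and 1 histone genes.

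**Figure D3:**
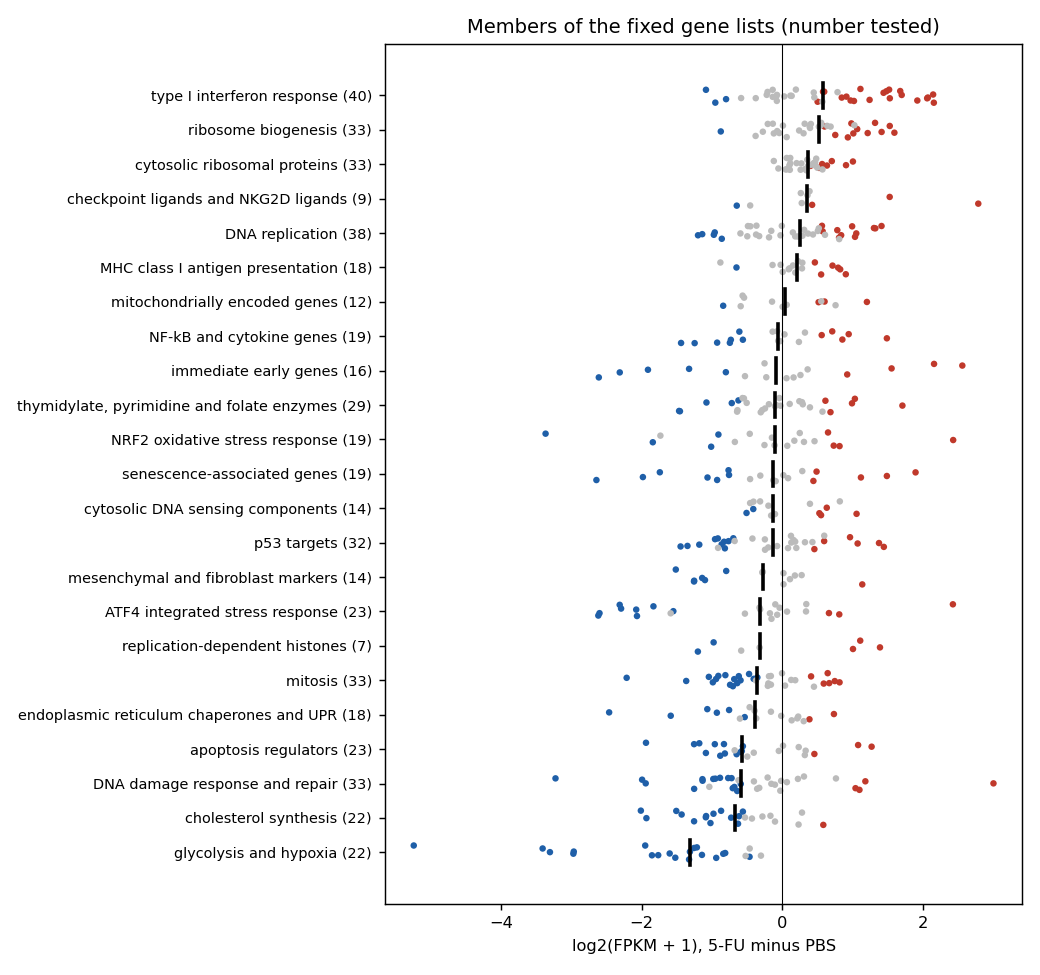
Members of the 23 lists with at least 5 tested genes. Each point is a gene at its difference of mean log2(FPKM + 1), 5-FU minus PBS (horizontal axis), in red where higher, blue where lower and grey where it did not pass the limma test. Black bars are list medians, and numbers in parentheses are genes tested. The glycolysis and hypoxia list has the lowest median (-1.32) and the type I interferon response the highest (0.573).

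Stress-response lists held large changes in opposite directions, in data where 53.3% of all tested genes passed. None of the 5 lists given here passed against other genes in the main camera test. Of 23 ATF4 target genes, 3 rose and 8 fell (camera adjusted p = 0.314, and 0.0243 without PBS replicate 1). The eIF2-alpha phosphatase subunit gene Ppp1r15a rose 5.50-fold, Atf4 rose from 337.7 ± 9.97 to 534.8 ± 16.9 FPKM and Slc3a2 by 0.809 log2, while Chac1, Vldlr and Trib3 fell by 2.62, 2.60 and 2.31 log2. Of 18 endoplasmic reticulum chaperone genes, 2 rose and 6 fell (camera adjusted p = 0.375). Xbp1, a transcription factor of the unfolded protein response, fell 6.31-fold, and Sdf2l1 and Sel1l fell by 1.59 and 1.07 log2, while Dnajb11 and Herpud1 rose by 0.733 and 0.385 log2, the call of Herpud1 being lost in 9 of 20 alternative settings. Of 19 NRF2 targets, 4 rose and 4 fell (camera adjusted p = 0.976). Osgin1 rose 6.09-fold, Txnrd1 and Prdx1 rose by 0.813 and 0.73 log2, and Srxn1, Gclc and G6pdx fell by 3.37, 1.84 and 1.01 log2. Of 16 immediate early genes, 4 rose and 5 fell (camera adjusted p = 0.976). Zfp36, Fosl1 and Egr1 rose by 2.56, 2.16 and 1.55 log2, and Jund, Klf4 and Klf2 fell by 2.61, 2.31 and 1.91 log2. Of 19 senescence-associated genes, 5 rose and 7 fell (camera adjusted p = 0.976). With no filter on low values 4 of 26 rose and 2 fell, and without mitochondrial and ribosomal protein genes 3 rose and 7 fell. The urokinase receptor gene Plaur rose 3.68-fold and Ereg 2.35-fold, and the cell cycle inhibitor genes Cdkn1b and Cdkn2b fell by 2.65 and 1.98 log2. Counts adjusted over the list alone were the same in these 5 lists. The counts higher and lower without PBS replicates 1 and 2 and 5-FU replicates 1 and 2 in turn were 5 and 15, 4 and 12, 1 and 8, and 1 and 8 for ATF4 targets, 4 and 10, 4 and 10, 0 and 2, and 0 and 2 for chaperones, 5 and 11, 10 and 7, 1 and 3, and 1 and 4 for NRF2 targets, 6 and 6, 7 and 7, 3 and 4, and 3 and 4 for immediate early genes, and 6 and 11, 7 and 9, 2 and 3, and 1 and 3 for senescence genes. In the p53, NF-kB, thymidylate, NRF2 and immediate early lists camera gave an upward direction while median and mean lay below 0, and in the DNA sensing and histone lists only the median lay below 0. Median-ratio scaling turned the median above 0 in the NF-kB, thymidylate, NRF2 and immediate early lists, and quantile normalization in the p53, NF-kB and immediate early lists.

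Of 16 epithelial markers, 1 was expressed highly enough to test, the tight junction gene Tjp1, which fell by 0.898 log2. Of 14 tested mesenchymal markers, 1 rose and 6 fell, likewise adjusted over the list alone (camera adjusted p = 0.375). S100a4, which begins 1069 bp after S100a3, rose from 204.6 ± 58.9 to 441.7 ± 18.2 FPKM, and Pdgfrb, Snai2 and Pdgfra fell by 1.52, 1.26 and 1.26 log2. This list held 3 higher and 7 lower without PBS replicate 1, 1 and 3 without 5-FU replicate 1, and 0 and 3 without 5-FU replicate 2. Of 3 tested leukocyte markers 0 passed, over all genes or over the list alone. Cd68 measured 6.29 and 19.3 FPKM in the PBS libraries and 18.0 and 16.1 in 5-FU, and Cd14 measured 11.4 ± 2.47 and 10.6 ± 0.838 FPKM (adjusted p = 0.38 and 0.718). The 1 tested endothelial or erythroid marker, Hba-a1, measured 2.05 ± 0.639 and 3.06 ± 0.357 FPKM (adjusted p = 0.132). Of 137 named genes past the threshold, 49 of 125 fitted lost it without 5-FU replicate 1, 48 of 125 without 5-FU replicate 2 and 0 of 129 without either PBS library, and none changed direction. Without a PBS library the error rests on the closer 5-FU pair and more genes pass, so keeping every call there is no sign of stability. Over 20 alternative settings (19 for Psmb10), calls were also lost in 6 for Psmb10, Ccl2 and Mre11a and in 5 for Herc6, Pole and Tnfrsf10b.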

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

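Voom, thinning, the length and GC trends, protein-coding genes only and the removal of genes after expressed genes were chosen after the results were seen. Of the 6206 genes past the threshold, 0 passed in the opposite direction under any setting, but the counts moved. Requiring a mean of 5 FPKM left 2158 genes lower, and 575 higher and 1036 lower by at least 1 log2, from 7651 tested genes. Leaving out 1 library gave 481 to 4428 genes higher, 1311 to 4624 lower, 476 to 1365 higher by at least 1 log2 and 1306 to 1539 lower by at least 1 log2. Without a 5-FU library the error rests on the wider PBS pair, and without a PBS library on the closer 5-FU pair. With replicate number as a block, 2484 genes were higher and 3553 lower; the correlation of deviations between equal numbers was -0.01, and nothing in the sources says that numbers mark pairs. For the changes with setting given in this part the cause was not tested.

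Fry asks whether a list changed at all, camera whether it changed against other genes, so their values answer different questions. Among lists past the threshold, none was left with an estimated correlation (0.989 each, type I interferon response included), the ribosome biogenesis list was lost with quantile normalization (0.0566), fry (0.232) and without PBS replicate 2 (0.146), and the ribosomal protein list with quantile normalization (0.739), fry (0.115) and without PBS replicate 1 (0.0587). Mitosis passed, lower, with no filter (0.0253), quantile normalization (0.0378) and fry (0.0451). DNA replication ranged over 0.0426 to 0.679 over left-out libraries and passed, higher, without PBS replicate 1. Also passing in single settings were DNA damage (no filter 0.0142, without PBS replicate 2 0.011), histones (no filter 0.0142, higher), apoptosis (no filter 0.0289, fry 0.0271), ATF4 targets (quantile 0.0378, without PBS replicate 1 0.0243), chaperones and ligands (fry 0.0271 each) and mesenchymal markers (fry 0.0478). The ribosomal protein and mitochondrially encoded lists had no value without these genes, the mitochondrially encoded list none without genes after an expressed gene, and the histone list none without a 5-FU library or at a mean of 5 FPKM, where under 5 members were tested.

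Directions turned only in results that did not pass, with adjusted p as follows. Where fry is listed, its direction is against no change and camera's against other genes, so it differs without being a turn of camera's result. For p53 targets it turned with no filter (0.785), with fry (0.313) and without PBS replicate 1 (0.707), in a range of 0.499 to 0.938 over left-out libraries. The thymidylate list turned with no filter (0.63), quantile normalization (0.786), fry (0.723) and without PBS replicate 2 (0.441), range 0.441 to 0.797. The NF-kB list turned with fry (0.649), without genes after an expressed gene (0.954) and without 5-FU replicate 1 (0.938) or 2 (0.79), range 0.707 to 0.938. NRF2 targets turned with the length trend removed (0.891), fry (0.524), a mean of 5 FPKM (0.895), no filter (0.785), quantile normalization (0.371), the block (0.97), without PBS replicate 1 (0.253) and without 5-FU replicate 2 (0.987), range 0.253 to 0.996. DNA sensing turned with no filter (0.884) and without PBS replicate 2 (0.935), range 0.407 to 0.935. Immediate early genes turned with the length trend removed (0.843), fry (0.0887), a mean of 5 FPKM (0.745), median-ratio scaling (0.959), no filter (0.884), quantile normalization (0.888) and without PBS replicate 1 (0.898), range 0.778 to 0.972. Histones ranged over 0.476 to 0.898 without a PBS library and turned without PBS replicate 1, and the mitochondrially encoded list turned with the length trend removed (0.719). Senescence genes turned with the GC trend removed (0.971), protein-coding genes only (0.825), voom (0.932), without genes after an expressed gene (0.966) and without mitochondrial and ribosomal protein genes (0.978). The log2 difference of Ccl5 was -0.25 with the length trend removed and -0.022 to 0.25 over left-out libraries. That of Cd14 was 0.031 with median-ratio scaling, 0.119 with quantile normalization, 0.002 after thinning and -0.289 to 0.12 over left-out libraries, and that of Cd68 was -0.173 to 1.302. All 3 turned without PBS replicate 1.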

Other observations

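The gene families named first and, of the tests of explanations, the neighbour test of protein-coding genes and the 2 tests of the glycolysis and hypoxia list were chosen only after the result was seen. The immunity-related GTPase genes, whose interferon-gamma-induced products attack vacuoles of intracellular microbes, were put together as a family after the rise of Ifi47 was seen, so their values are given without a test of the family. All 7 tested rose after 5-FU, with a median of 2.22 log2, and all 7 also rose with median-ratio scaling, with quantile normalization and without either PBS library (4 of 5 tested without either 5-FU library). Igtp went from 9.98 ± 4.06 to 60.9 ± 3.79 FPKM, Irgm1 from 10.1 ± 4.77 to 48.2 ± 0.717 and Tgtp2 from 0.345 ± 0.118 to 7.69 ± 0.309 (mean ± SD, n = 2 per group). Tgtp1 and Tgtp2 are near-identical, so single values of these genes are uncertain.

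Also chosen after their values were seen, 12 of 21 genes whose symbols begin with Cox, mostly cytochrome c oxidase subunits, rose and 0 fell (camera adjusted p = 0.00128 over 67 families; 0.955 with an estimated correlation). Cox5b went from 265.6 ± 6.91 to 434.2 ± 12.1 FPKM and Cox4i1 from 203.3 ± 1.38 to 298.6 ± 11. No Cox gene passed without either 5-FU library (0 of 21), and 9 passed with quantile normalization. Of 18 genes with the prefix Col, nearly all collagens, 10 fell and 0 rose (camera adjusted p = 0.016; 0.955 with an estimated correlation). Col4a5 went from 23.2 ± 9.57 to 4.43 ± 0.273 FPKM and Col6a3 from 24.3 ± 0.37 to 9.89 ± 0.271. Neither the Cox nor the Col family was rerun with the trend with exonic length removed. Long genes fell more often (61.1% at 200 kb or more, 25.4% under 10 kb), and the part of gene length in both families was not tested. Under median-ratio scaling and quantile normalization 10 Col genes fell as well, and 5 did without either 5-FU library. Of 533 processed pseudogenes, 229 were higher and 31 lower, with a median of 0.477 log2. The counts were 280 and 25 with median-ratio scaling and 301 and 22 with quantile normalization. Without mitochondrial and ribosomal protein genes, 160 of 449 were higher and 28 lower. The median was 0.44 and 0.408 without 5-FU replicates 1 and 2, where far fewer of them passed. It was 0.537 and 0.522 without PBS replicates 1 and 2.

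Several near-silent genes that rose, Gp5, Cdo1 and Mss51 among them, lie just after an expressed gene. Of 64 near-silent protein-coding genes that rose, 26 (40.6%) began within 10 kb after an expressed gene on the same strand, against 4.2% of 10838 others (odds ratio 15.62, 95% interval 9.44 to 25.84, Fisher exact test p = 4.17e-19), while 3.1% and 3.9% ended before one and an expressed gene on the opposite strand lay upstream more often too (odds ratio 3.63, 1.5 to 8.76, Fisher exact test p = 0.0221). Genomic DNA in the 5-FU libraries stays open. Of 6862 silent genes without an expressed gene within 50 kb, 0.26% (0.16 to 0.41) reached 3 FPKM in 5-FU. DNA spread thinly over the genome need not lift any gene that far, so this share cannot decide. Reads running past the end of an upstream gene may account for part of these rises: other gene models were enriched there too (odds ratio 12.56, 4.93 to 31.99, Fisher exact test p = 0.000147), though also beside genes on the opposite strand (20.54), and whether reads were counted by strand is not given in the sources used here. Whether such reads reach beyond 10 kb cannot be told apart, as the odds ratio of 1.01 has an interval (0.34 to 3.04) that also holds a 3-fold excess, so the bound set beforehand, an interval reaching 1, was too weak to exclude it.

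Long genes were lower in 5-FU, with a Spearman correlation between log2 difference and gene span of -0.251 across 10354 genes, which are not independent replicates. The lower depth of the 5-FU libraries is argued against, because the correlation was -0.252 (-0.273 to -0.234) after thinning all libraries to the smallest. Loss or fragmentation of long mRNAs could contribute, as the partial correlation with exonic length given intronic length was -0.14 (-0.158 to -0.122). Impaired transcription through long introns stays open. The partial correlation with intronic length given exonic length was -0.115 (-0.132 to -0.095), which lies below 0 but does not clear the bound set beforehand (-0.1). Its interval overlaps that of exonic length, so the 2 lengths cannot be ranked. The 165 single-exon genes, which have no introns, were lower as well (median -0.64, 46.7% lower, against -0.15 and 33.0% with 2 or more exons). Whether 5-FU itself acts on long transcripts was not tested, and all libraries of a group share whatever differed in their preparation.

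The glycolysis and hypoxia genes, Bnip3 and Pdk1 among them, had a median log2 difference of -1.32 and were higher in PBS replicate 2 than in replicate 1 (21 of 22 genes). PBS replicate 2 alone is argued against as the source, because the median against PBS replicate 1 was -1.164 (95% interval -1.692 to -0.709), and so is the trend with exonic length, with a median of -1.227 (-1.891 to -1.032) once it was removed. The oxygen or nutrient state of the PBS cultures stays open and was not tested, since nothing separates it from the treatment, and culture density was not analysed here. An effect of 5-FU itself also stays open.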
